A study of Ambystoma mexicanum with 17 samples.

How the data were processed

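Polyadenylated RNA from forelimb tissue was sequenced in 17 libraries, 3 of uninjured tissue, 5 of anterior blastemas, 4 of posterior blastemas and 5 of posterior blastemas with 25 uM U0126. Groups were taken from the labels alone. The labels name Holtfreter's solution and DMSO beside the inhibitor, and which of these the untreated posterior blastemas received is not clear from them. Per the submitters' processing notes, reads were trimmed with Trimmomatic 0.39 and aligned with STAR 2.7.3a; the genome build and annotation are not given in the sources used here, so no coordinates are reported. The deposited files hold raw counts per gene, not normalized, as the authors' alignment gave them, with 3 columns for unstranded and both stranded ways of counting, and 4 totals of reads outside genes. Those totals (14.2% to 16.4% of reads) were left out of library sizes and tests. The ratio of reads on the second to the first strand was 1.90 to 2.16, below the value of 3 set beforehand for a stranded library, so the unstranded counts were used; without strand, reads of overlapping and antisense genes cannot be told apart.

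Each file held 122775 unique gene IDs. Of the 67180 outside tRNA, 67156 were found in a RefSeq gene table used only for names. Of 529 symbols in 29 gene lists fixed before the data were examined, 431 were in the files, and 28 lists had at least 3 tested members. The lists cover posterior, anterior, proximal and distal limb patterning, hedgehog targets, retinoic acid, ERK feedback, FGF, WNT, BMP and TGF-beta, NOTCH, cell cycle, blastema mesenchyme, wound epithelium, differentiated epidermis, matrix remodelling, connective tissue matrix, skeletal muscle, muscle progenitors, cartilage and bone, Schwann cells and nerve, endothelium, macrophages and granulocytes, lymphocytes, red blood cells, pigment cells, stress, mitochondrially encoded genes and chromatin. The red blood cell list had 2 tested genes and no test. Libraries held 34181446 to 53856865 counts in genes, 83.6% to 85.8% of their reads. Pairs of replicates differed by more than sampling noise (chi-square per degree of freedom 80 to 796), so no library was counted as a repeat of another.

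Genes were filtered with edgeR's filterByExpr, leaving 19398 genes, 12372 of them with a symbol. Counts were scaled with TMM (factors 0.862 to 1.08) and fitted in 1 model of all 4 groups with edgeR 4.0.16 in R 4.3.3 (robust quasi-likelihood fit and F test), with Benjamini-Hochberg adjustment and a threshold of 0.05. The common biological coefficient of variation was 0.447 and the median prior degrees of freedom 2.31. The SE of a log2 fold change is the value implied by the F test, the absolute log2 fold change divided by the square root of F. It was not estimated separately and is not independent of the p-value. Gene lists were tested with camera of limma 3.58.1 at a preset correlation of 0.01 and again with an estimated one, adjusted over 28 lists per comparison. Later lists of NRF2 and aryl hydrocarbon receptor targets were adjusted over those lists alone. CPM (edgeR's cpm function) are counts per 1000000 of the TMM-scaled library total, computed from the deposited counts. Named genes were, per comparison, the 10 highest and 10 lowest log2 fold changes among genes with a symbol, an adjusted p under 0.05, a mean of at least 1 log2 CPM and no overlap between groups, up to 4 genes of each list with the smallest adjusted p, and a fixed set of limb genes; the text gives a selection of these. For SHH, with few reads, summed reads are given in place of a fold. Tests were checked on simulated counts, in which 1 to 5 unchanged genes were called per comparison. Genes were drawn independently of each other, without any library that stood apart, and only genes above a minimum mean count were changed. False calls and recovery in the real data can thus be worse.

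Fold changes that share libraries were set against 100 simulations of groups without effect. Alternatives were RLE and total-count scaling, no filter and a stricter one (CPM of 1 in 3 libraries), another count column, only the 2 groups compared, the replicate number as a block, a 2-fold minimum, DESeq2 1.42.0 and leaving out each library; leaving out the libraries labelled uninjured replicate 1 and inhibitor replicate 5 was added after the data were seen. Summing counts of IDs with 1 symbol changed nothing because symbols were unique. The plot of gene levels was drawn with matplotlib 3.10.9 in Python 3.11.15.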

Results

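RNA was measured in regenerating and uninjured forelimb tissue of white (d/d) axolotls. Accessory limb outgrowths (blastemas) had been induced by deviating a nerve and were collected with their wound epithelium 10 days after injury. The 17 libraries fell into 4 groups: uninjured tissue (n = 3), anterior blastemas (n = 5), posterior blastemas (n = 4) and posterior blastemas exposed to 25 uM U0126, an inhibitor of the kinases that activate ERK (n = 5). Each library held between 34181446 and 53856865 reads counted in genes. Of the genes, 19398 had enough reads to be tested. The labels do not say that the libraries of a group came from separate animals, so the p-values measure the spread between these libraries. The library labelled uninjured replicate 1 and the library labelled inhibitor replicate 5 stood apart from their groups. TNC, a matrix glycoprotein gene chosen after its values were seen, shows this. It was at 1329 CPM (counts per 1000000 of the scaled library total) in the first, against 71.6 and 78.4 CPM in the other uninjured libraries. In the second it was at 102 CPM, against 444 to 1135 CPM in the other inhibitor libraries. Every comparison with these groups carries that doubt.

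Which genes set posterior apart from anterior blastemas was the first question. The transcription factor LHX9 was lower in posterior blastemas, at 0.213 ± 0.134 CPM (SD, n = 4), than in anterior blastemas, at 16.8 ± 6.49 CPM (SD, n = 5). Its log2 fold change was −6.31 ± 0.87 (SE), with an adjusted p of 0.049997, just under the threshold, in edgeR's quasi-likelihood test. It was lower in 4 of 4 posterior libraries than in every anterior library. The genes of the hedgehog pathway, through which posterior limb cells signal, had higher mean levels on the posterior side without passing the test singly. The hedgehog receptor PTCH1 was at 28.3 ± 20.6 CPM (SD, n = 4) against 3.04 ± 1.19 CPM (SD, n = 5). The transcription factor GLI1 had a log2 fold change of 2.52 ± 0.57 (SE). SHH, the hedgehog ligand of the posterior limb margin, had 560 reads in the posterior libraries together, 342 of them in replicate 1 and 5 in replicate 4, and 2 reads in the anterior libraries together. HAND2, a regulator upstream of SHH, was at 19.2 ± 9.75 CPM (SD, n = 4) against 2.12 ± 1.22 CPM (SD, n = 5).

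By camera with a preset correlation, the hedgehog targets rose as a list (median log2 fold change 2.87 over 4 genes, adjusted p = 3.28e-09; adjusted p = 0.0738 with an estimated correlation). For 3 of the 4 the change passed when adjusted over the list alone, against 0 over all genes tested. The posterior patterning list also rose (median log2 fold change 1.60 over 11 genes, adjusted p = 6.36e-07; adjusted p = 0.282 with an estimated correlation). Its calls were SHH, HOXD13, TBX3 and HAND2 (4) adjusted over the list alone and 0 over all genes. The anterior patterning list fell (median log2 fold change −0.76 over 14 genes, adjusted p = 3.83e-05; adjusted p = 0.104 with an estimated correlation). Adjusted over the list alone, LHX9, ALX4 and ALX1 were lower and PAX1 was higher; over all genes LHX9 was the 1 call. ALX4, a transcription factor of the anterior limb, had a log2 fold change of −1.51 ± 0.32 (SE). The growth factor gene FGF8 was at 0.638 ± 0.537 CPM (SD, n = 4) against 2.36 ± 1.92 CPM (SD, n = 5).

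Skeletal muscle genes were higher in the posterior libraries in all 22 members measured (median log2 fold change 3.12, camera adjusted p = 3.72e-25; adjusted p = 0.137 with an estimated correlation). Genes of muscle progenitors were higher in all 6 (median 2.67, adjusted p = 5.37e-09; adjusted p = 0.104 with an estimated correlation). The share of counts in the skeletal muscle genes ran from 0.218% to 1.63% in posterior and from 4.31e-04% to 0.410% in anterior libraries. Connective tissue matrix (median 0.68, adjusted p = 8.09e-08), WNT (median 0.21, adjusted p = 0.0111) and proximal patterning genes (median 0.38, adjusted p = 0.0176) also rose by camera with a preset correlation. Cell cycle (median −0.18, adjusted p = 0.00720) and differentiated epidermis genes (median −0.67, adjusted p = 1.23e-04) fell. With an estimated correlation these had adjusted p = 0.282, adjusted p = 0.415, adjusted p = 0.472, adjusted p = 0.777 and adjusted p = 0.137. The genes of the distal limb were not called as a list (adjusted p = 0.382 by camera), with 5 of 13 past the threshold adjusted over the list alone and 1, LHX9, over all genes. HOXA13 had a log2 fold change of 3.35 ± 0.76 (SE) and HOXA11 one of 2.54 ± 0.85 (SE), and neither passed over all genes. MEIS1 (log2 fold change −0.27 ± 0.20, SE) and MEIS2 (−0.64 ± 0.24, SE), regulators of the upper limb, did not pass either. The same held for the enzymes of retinoic acid synthesis and breakdown ALDH1A2 (1.62 ± 0.63, SE), CYP26A1 (−2.37 ± 0.92, SE) and CYP26B1 (−1.05 ± 0.51, SE).

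With edgeR, 1 of the 19398 genes passed, lower in posterior blastemas, and 0 passed as higher. No overlap between the groups was seen in 4.85% of all genes tested, where chance gives 1.59%. At an unadjusted p under 0.05 there were 1855 genes, 1078 of them higher, and DESeq2 called 132 genes, 95 of them higher. Without both doubted libraries, a setting chosen after seeing the data, edgeR called 1 gene, LHX9. Leaving out any 1 of the 9 posterior or anterior libraries left 0 calls in edgeR, with an adjusted p for LHX9 between 0.0518 and 0.243. Over the alternatives in which this gene was followed its adjusted p ran from 1.59e-15 with DESeq2 to 0.243. Total-count scaling and no filter, in which edgeR called 0 genes, and the stricter filter are not in that range. On simulated counts for this comparison, with genes drawn independently, 36 of 100 genes changed 2-fold and 69 of 100 changed 4-fold were recovered. Recovery among the real genes can be lower.

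The next comparison asked what the inhibitor changed in posterior blastemas. Feedback genes of ERK signalling fell as a list (median log2 fold change −0.82 over 20 genes, camera adjusted p = 8.50e-06; adjusted p = 0.0313 with an estimated correlation). Without both doubted libraries the latter was 0.169 by camera. PHLDA1, an immediate early gene, fell from 48.3 ± 6.76 CPM (SD, n = 4) to 15.4 ± 7.12 CPM (SD, n = 5), and the ephrin receptor EPHA4 fell with a log2 fold change of −2.13 ± 0.46 (SE). These were the 2 calls in the list over all genes, and 10 members were lower when adjusted over the list alone. The feedback inhibitors SPRY2 (log2 fold change −0.83 ± 0.29, SE) and SPRY4 (−0.88 ± 0.29, SE) and the ERK target ETV4 (−0.92 ± 0.37, SE) did not pass over all genes. The ERK phosphatase DUSP6 and the factor ETV5 are not among the symbols of the count files used here.

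Genes of posterior identity were lower with the inhibitor. TBX3 fell with a log2 fold change of −1.58 ± 0.33 (SE) and PTCH1 with one of −2.21 ± 0.61 (SE). The posterior list had a median log2 fold change of −1.73 with 11 of 11 members lower (camera adjusted p = 1.96e-06; adjusted p = 0.190 with an estimated correlation). The hedgehog targets had a median of −1.85 (adjusted p = 0.00182; adjusted p = 0.190 with an estimated correlation). Over all genes 1 posterior and 2 hedgehog genes passed, and 7 and 3 adjusted over the list alone. SHH had 63 reads in the inhibitor libraries together, 51 of them in replicate 4, against 560, 342 of them in posterior replicate 1. HAND2 was at 3.66 ± 5.02 CPM (SD, n = 5) against 19.2 ± 9.75 CPM (SD, n = 4); neither passed. In the library labelled inhibitor replicate 4, HAND2 was at 12.4 CPM and PTCH1 at 15.2 CPM, the highest of its group. Proximal limb genes fell as a list (median −1.65 over 12 genes, adjusted p = 1.96e-06; adjusted p = 0.155 with an estimated correlation). Its calls were SHOX (log2 fold change −1.99 ± 0.46, SE), SHOX2 (−2.09 ± 0.53, SE) and TBX5 (−1.83 ± 0.50, SE), with 8 adjusted over the list alone. Distal genes fell as a list too (median −1.34, adjusted p = 0.00182; adjusted p = 0.299 with an estimated correlation), with 0 calls in edgeR over all genes and 0 adjusted over the list alone. HOXA13 had a log2 fold change of −1.87 ± 0.72 (SE) and HOXA11 one of −1.79 ± 0.84 (SE).

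**Figure D1:**
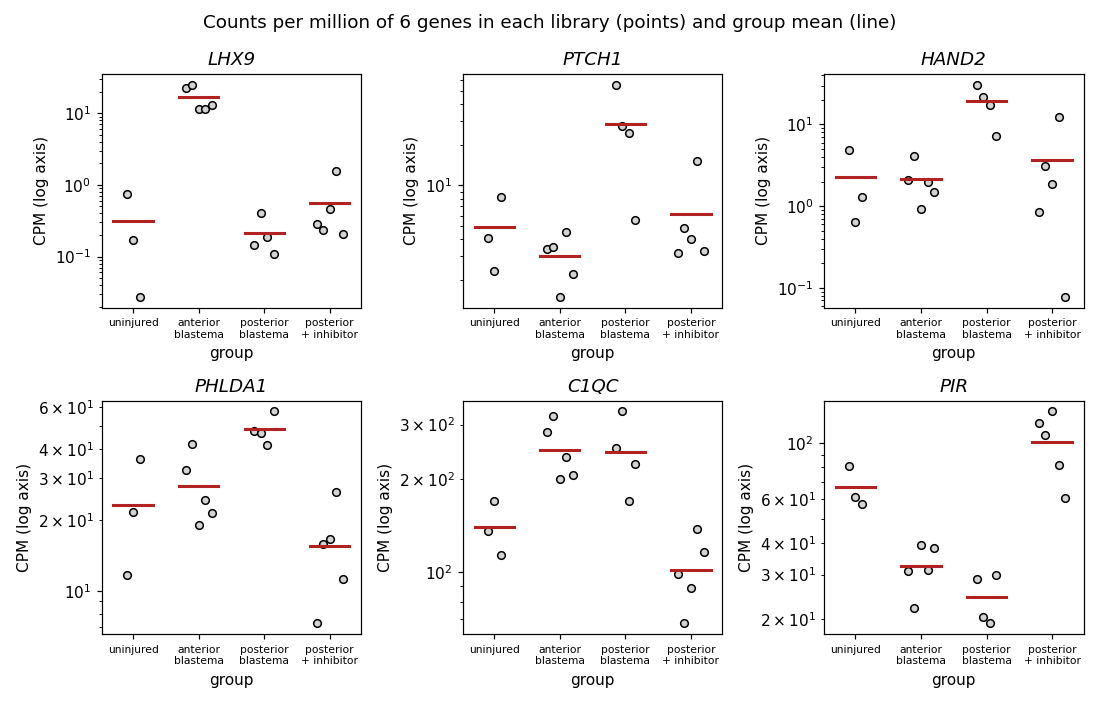
CPM (log axis) of 6 genes in each of the 17 libraries (points), by group, with the group mean (line). LHX9 was between 11.5 and 25.0 CPM in the 5 anterior blastema libraries and between 0.109 and 0.408 CPM in the 4 posterior ones, and PIR was between 60.5 and 134 CPM in the 5 inhibitor libraries and between 19.2 and 29.9 CPM in the 4 posterior ones.

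Genes of mesenchyme and matrix fell together with the patterning genes under the inhibitor. The blastema mesenchyme list fell (median log2 fold change −1.35 over 15 genes, camera adjusted p = 6.10e-07; adjusted p = 0.155 with an estimated correlation), with 4 calls and 9 adjusted over the list alone. The homeobox gene PRRX2 fell from 148 ± 68.5 CPM (SD, n = 4) to 29.2 ± 29.5 CPM (SD, n = 5), and the secreted glycoprotein gene FSTL1 fell with a log2 fold change of −1.48 ± 0.33 (SE). Connective tissue matrix genes fell (median −1.05 over 22 genes, adjusted p = 1.63e-08; adjusted p = 0.190 with an estimated correlation), with 7 calls and 13 adjusted over the list alone. The calls included the collagen genes COL6A1 (−1.75 ± 0.37, SE) and COL5A2 (−1.27 ± 0.27, SE). Matrix remodelling genes (median −1.02, adjusted p = 3.38e-05; adjusted p = 0.190 with an estimated correlation) fell as well, with 2 calls and 6 adjusted over the list alone. So did cartilage and bone genes (median −0.83, adjusted p = 9.57e-05; adjusted p = 0.0793 with an estimated correlation), with 4 calls and 8 adjusted over the list alone. The genes of complement component C1q, made by macrophages, fell. C1QA (−1.39 ± 0.27, SE), C1QB (−1.33 ± 0.23, SE) and C1QC (−1.26 ± 0.22, SE) were the 3 calls of the macrophage list (median −0.67, adjusted p = 1.41e-06; adjusted p = 0.190 with an estimated correlation), with 5 adjusted over the list alone.

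The retinoic acid list (median −0.60, adjusted p = 0.00593), the WNT list (median −0.56, adjusted p = 0.00831) and the BMP and TGF-beta list (median −0.76, adjusted p = 8.11e-04) also fell by camera with a preset correlation. These had adjusted p = 0.190, adjusted p = 0.290 and adjusted p = 0.190 with an estimated correlation. The retinoic acid list held 2 calls, the synthesis enzyme ALDH1A3 (log2 fold change −2.19 ± 0.43, SE) and the receptor RARA (−1.19 ± 0.28, SE), and 4 genes adjusted over the list alone. Differentiated epidermis (median 0.71, adjusted p = 0.00268), stress response (median 0.42, adjusted p = 0.0122) and cell cycle genes (median 0.21, adjusted p = 0.0214) rose by camera with a preset correlation. With an estimated correlation these had adjusted p = 0.190, adjusted p = 0.295 and adjusted p = 0.709. GRHL1, an epidermal transcription factor, rose (0.96 ± 0.20, SE), as did the stress genes MDM2 (0.51 ± 0.12, SE), HSP90AA1 (0.92 ± 0.26, SE) and DDIT3 (1.16 ± 0.34, SE). The lists of FGF signals (camera adjusted p = 0.0836), NOTCH (0.269), wound epithelium (0.185), anterior patterning (0.0755), skeletal muscle (0.0797) and muscle progenitors (0.150) were not called. Neither were those of Schwann cells and nerve (camera adjusted p = 0.774), endothelium (0.0836), lymphocytes (0.950), pigment cells (0.685), mitochondrially encoded genes (0.894) and chromatin regulators (0.685).

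Among all genes, the largest rises of the named set under the inhibitor included MFAP3L (log2 fold change 2.42 ± 0.44, SE), the monocarboxylate carrier gene SLC16A14 (2.36 ± 0.62, SE) and the mitochondrial carbonic anhydrase gene CA5A (2.22 ± 0.46, SE). The transketolase gene TKT (2.12 ± 0.39, SE), PIR (2.04 ± 0.24, SE) and AHRR (1.86 ± 0.41, SE), the repressor of the aryl hydrocarbon receptor, rose too. The largest falls included ODAM (−4.67 ± 1.35, SE), RGS4 (−3.92 ± 0.90, SE), MATN4 (−3.01 ± 0.61, SE), SIM2 (−2.51 ± 0.73, SE) and the ephrin receptor gene EPHA7 (−2.25 ± 0.47, SE). Having no overlap between the libraries of both groups was part of the rule that named these 11 genes, so it is no further support for them.

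In all, 1576 genes passed in edgeR, 802 higher and 774 lower, 699 of them by at least 2-fold. Of all genes tested, 12.3% had no overlap between the groups, where chance gives 1.59%. With total counts in place of TMM scaling the split was 440 higher and 736 lower. DESeq2 called 2903 genes. Without both doubted libraries edgeR called 2575. The count was 127, 307 and 850 without posterior replicates 1, 2 and 3, 450, 698 and 678 without inhibitor replicates 1, 2 and 3, and was 2381 without inhibitor replicate 4. On simulated counts for this comparison, again with genes drawn independently, 43 of 100 genes changed 2-fold and 77 of 100 changed 4-fold were recovered. Real genes can be recovered less often.

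The comparison of anterior blastemas with uninjured tissue asked what regeneration changed on the anterior side. LHX9 rose from 0.316 ± 0.380 CPM (SD, n = 3) to 16.8 ± 6.49 CPM (SD, n = 5), and ALX4 rose with a log2 fold change of 2.24 ± 0.38 (SE). MECOM, a zinc finger transcription factor, rose by 4.35 ± 0.73 (SE) on the log2 scale. CORO2B (3.66 ± 0.70, SE), INKA1 (1.71 ± 0.31, SE) and the laminin receptor gene BCAM (1.18 ± 0.22, SE) rose too. The tyrosine aminotransferase gene TAT (−3.48 ± 0.57, SE), the amino acid transporter genes SLC38A4 (−1.93 ± 0.35, SE) and SLC6A9 (−1.17 ± 0.17, SE) and the EGF receptor inhibitor gene LRIG1 (−1.84 ± 0.34, SE) fell. So did the regulatory subunit genes of phosphoinositide 3-kinase PIK3R1 (−1.48 ± 0.26, SE) and PIK3R2 (−1.33 ± 0.25, SE). The ERK feedback list rose (median 0.97, 19 of 20 members higher, camera adjusted p = 1.59e-06; adjusted p = 0.0180 with an estimated correlation), with 0 members past the edgeR test over all genes and 8 adjusted over the list alone. Camera's adjusted p with an estimated correlation was 0.229 without both doubted libraries. FOSL1 had a log2 fold change of 3.94 ± 0.97 (SE) and EPHA2 one of 1.54 ± 0.45 (SE).

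Anterior patterning (median log2 fold change 1.78, 2 calls, camera adjusted p = 8.01e-05), blastema mesenchyme (14 of 15 higher, adjusted p = 6.73e-08), matrix remodelling (median 1.09, adjusted p = 7.47e-06) and macrophage genes (median 0.68, adjusted p = 1.39e-04) rose as lists with a preset correlation. These had adjusted p = 0.160, adjusted p = 0.160, adjusted p = 0.186 and adjusted p = 0.405 with an estimated correlation. Adjusted over the list alone, 9, 6, 4 and 4 of their genes passed, 2 of the anterior genes being lower. The lists of cell cycle (adjusted p = 8.01e-05), distal patterning (adjusted p = 0.00103), BMP and TGF-beta (adjusted p = 0.00407), wound epithelium (adjusted p = 0.0127), posterior patterning (adjusted p = 0.0152) and chromatin genes (adjusted p = 0.0204) rose by camera with a preset correlation. With an estimated correlation all of these had adjusted p between 0.189 and 0.652. Skeletal muscle genes fell (median −3.96, 22 of 22 lower, adjusted p = 1.03e-14; adjusted p = 0.282 with an estimated correlation), with 20 genes adjusted over the list alone and 0 over all genes in edgeR. Muscle progenitor genes fell (median −1.97, adjusted p = 8.87e-04; adjusted p = 0.357 with an estimated correlation). The skeletal muscle share of the library labelled uninjured replicate 1 was 0.111% of counts, against 1.55% and 3.37% in the other uninjured libraries.

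In edgeR 40 genes passed, 13 higher and 27 lower. Of all genes tested, 10.7% had no overlap between the groups, where chance gives 3.57%. With total counts the split was 44 higher and 30 lower, with the median of all genes at 0.12 on the log2 scale. DESeq2 called 1673 genes, and 4163 had an unadjusted p under 0.05. The edgeR count was 3675 without the library labelled uninjured replicate 1, 0 without uninjured replicate 2 or 3 or anterior replicate 2 or 5, 2 without anterior replicate 1, 24 without anterior replicate 4 and 4492 without both doubted libraries.

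Posterior blastemas were set against uninjured tissue as well. The names of all 3 uninjured libraries start with A, like those of the anterior blastemas, and the names of the posterior libraries start with P. The labels do not say what these letters mark. In this comparison, a difference in limb side or animal thus cannot be told apart from a change with injury. The matrix protease genes CTSK (log2 fold change 1.86 ± 0.38, SE) and MMP2 (1.68 ± 0.41, SE) rose, as did TBX3, from 9.46 ± 2.89 CPM (SD, n = 3) to 32.9 ± 17.9 CPM (SD, n = 4). Angiopoietin 1 (ANGPT1, 2.72 ± 0.63, SE), the endothelial tight junction gene CLDN5 (2.46 ± 0.59, SE) and the ephrin receptor gene EPHA7 (2.57 ± 0.58, SE) rose. The neurotrophic factor gene ARTN (2.16 ± 0.41, SE), the oxidase gene NOX4 (2.15 ± 0.48, SE) and HOXD3 (2.13 ± 0.51, SE) rose too. MFAP3L (−2.73 ± 0.47, SE), TAT (−2.64 ± 0.60, SE), MAP2 (−2.08 ± 0.38, SE), the circadian repressor gene CRY1 (−1.94 ± 0.42, SE) and the epidermal genes PPL (−1.28 ± 0.24, SE) and GRHL1 (−1.06 ± 0.22, SE) fell. The ERK feedback list rose (median 1.09, 19 of 20 members higher, camera adjusted p = 4.30e-08; adjusted p = 0.00785 with an estimated correlation), with 0 edgeR calls over all genes and 16 adjusted over the list alone, 15 of them higher. Camera's adjusted p with an estimated correlation was 0.115 without both doubted libraries.

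Posterior patterning (median log2 fold change 2.57, 11 of 11 higher, camera adjusted p = 4.30e-08), blastema mesenchyme (median 1.57, adjusted p = 4.30e-08) and matrix remodelling genes (median 1.47, adjusted p = 4.91e-08) rose as lists with a preset correlation. With an estimated correlation these had adjusted p = 0.269, adjusted p = 0.153 and adjusted p = 0.153. In edgeR over all genes they held 1, 0 and 2 calls, and 7, 9 and 9 adjusted over the list alone. Distal (adjusted p = 1.70e-04), proximal (adjusted p = 8.61e-04), BMP and TGF-beta (adjusted p = 8.05e-04), connective tissue (adjusted p = 0.00259), macrophage (adjusted p = 0.00259) and hedgehog target genes (adjusted p = 0.00867) rose by camera with a preset correlation. Differentiated epidermis genes (adjusted p = 0.00127) fell. With an estimated correlation all of these had adjusted p between 0.269 and 0.523. Without both doubted libraries, connective tissue (camera adjusted p = 0.429) and hedgehog target genes (camera adjusted p = 0.192) were no longer called with a preset correlation.

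In edgeR 408 genes passed, 168 higher and 240 lower. Of all genes tested, 16.7% had no overlap between the groups, where chance gives 5.71%. With total counts the split was 173 higher and 100 lower, with the median of all genes at 0.14 on the log2 scale. DESeq2 called 1949 genes, and 4125 had an unadjusted p under 0.05. The edgeR count was 1935 without the library labelled uninjured replicate 1, 4 without uninjured replicate 2, 0 without uninjured replicate 3 or posterior replicate 1 or 2, 114 without posterior replicate 3 and 3108 without both doubted libraries.

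Calls against the shared uninjured libraries overlapped between anterior and posterior blastemas in 9 higher and 17 lower genes; shared libraries give overlap by themselves, and no simulation was run for these counts. Across genes, which are not independent replicates, the fold changes had a covariance of 0.435 against 0.191 in groups simulated without effect, a difference of 0.245. They had a Pearson r of 0.619 against 0.603 simulated.

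Inhibitor-treated posterior blastemas were also set against anterior blastemas. LHX9 (log2 fold change −4.92 ± 0.72, SE), MECOM (−3.54 ± 0.56, SE), MAB21L2 (−3.82 ± 0.61, SE), ALX4 (−2.21 ± 0.31, SE) and GLI3 (−1.41 ± 0.30, SE) were lower in treated posterior tissue. The anterior patterning list was lower (median −1.81, 3 calls, 8 adjusted over the list alone, camera adjusted p = 6.63e-09; adjusted p = 0.0126 with an estimated correlation). So was the ERK feedback list (median −0.82, 0 edgeR calls, 2 adjusted over the list alone, adjusted p = 8.71e-06; adjusted p = 0.0152 with an estimated correlation). Without both doubted libraries these had camera adjusted p = 0.0753 and adjusted p = 0.130 with an estimated correlation. The 3 C1q genes and the macrophage growth factor receptor gene CSF1R (−0.91 ± 0.19, SE) were lower. The porphyrin transporter gene ABCB6 (1.91 ± 0.25, SE), LONRF1 (2.34 ± 0.31, SE) and PIR (1.64 ± 0.22, SE) were higher. HAND2 (0.78 ± 0.86, SE) and HOXA11 (0.75 ± 0.80, SE) did not pass, and each turned negative without inhibitor replicate 4 (−0.53 and −0.30). Blastema mesenchyme (adjusted p = 5.12e-09) and macrophage genes (adjusted p = 9.86e-12) fell by camera with a preset correlation, and each had adjusted p = 0.0872 with an estimated one. Called with the preset correlation only, proximal, retinoic acid and matrix remodelling genes (each adjusted p = 2.92e-04) fell. So did BMP and TGF-beta, and cartilage and bone genes (each adjusted p = 0.00107), and distal genes (adjusted p = 0.00211). Connective tissue (adjusted p = 0.00767) and wound epithelium genes (13 of 18 lower) also fell with it. Skeletal muscle (adjusted p = 2.85e-11), muscle progenitor (adjusted p = 0.00111) and stress genes (adjusted p = 0.00998) rose with it. With an estimated correlation all of these had adjusted p between 0.0872 and 0.529.

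In edgeR 229 genes passed, 109 higher and 120 lower. Of all genes tested, 4.40% had no overlap between the groups, where chance gives 0.794%. DESeq2 called 1232. Without both doubted libraries the count was 898. Without inhibitor replicate 4 it was 828, and without inhibitor replicate 5 it was 430. Without inhibitor replicates 1, 2 and 3 it was 46, 54 and 47. Without anterior replicates 1, 2, 4 and 5 it was 49, 36, 78 and 63. The calls overlapped with those of the inhibitor against posterior blastemas in 88 higher and 95 lower genes; both comparisons share the inhibitor libraries, which gives overlap by itself, and no simulation was run for it.

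Whether the inhibitor moved posterior tissue toward anterior levels was asked of the genes that differed between both sides. The 1 such gene, LHX9, had the direction of anterior levels without passing the edgeR test (log2 fold change 1.39 ± 0.76, SE). It was at 0.552 ± 0.587 CPM (SD, n = 5) with the inhibitor, against 0.213 ± 0.134 CPM (SD, n = 4) without it and 16.8 ± 6.49 CPM (SD, n = 5) in anterior blastemas. Inhibitor replicate 4 was at 1.59 CPM and the other 4 at 0.206 to 0.456 CPM. Over all genes, which are not independent replicates, 73.2% had the direction of anterior, against 68.8% in groups simulated without effect that shared the posterior libraries. The covariance of both fold changes was 0.282 against 0.140 simulated, a difference of 0.142, while Pearson's r was 0.517 against 0.555 simulated. With the posterior libraries split so that none was shared, the mean covariance of 6 splits was 0.175 (range 0.0605 to 0.238), against −8.92e-04 simulated.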

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

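The tests of explanations for the 3 patterns below were chosen only after the results were seen, and the lists of NRF2 and aryl hydrocarbon receptor targets were written after the values of many genes, 11 of their members included, had been looked at.

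LHX9 rose from uninjured tissue by 5.71 on the log2 scale in anterior blastemas and not in posterior blastemas (−0.61), a difference of −6.31 between both groups (edgeR adjusted p of 0.049997; 1.59e-15 to 0.243 over the alternatives in which the gene was followed, not counting total-count scaling and the filter settings, and above 0.05 without any 1 of the 9 anterior or posterior libraries).

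Anterior, posterior and inhibitor libraries were searched for a library far from the others of its group, and uninjured libraries were not. A chance rate of 1 in 20, which would give 12.6, holds only for independent values with a normal spread. The values were mostly CPM of single genes, which need not be normal and can move together, so an excess over that rate shows nothing by itself. Of 251 groups of values tested, 35 held such a library. The library labelled inhibitor replicate 4 held 17 of them, all highest in its group: COL11A1 383 CPM, CORO2B 5.16, EPHA4 12.1, FGF8 0.831, GLI1 3.93, GLI3 22.1, HAND2 12.4, HOXA11 8.16, IL17RD 14.9, LHX9 1.59, MATN4 1.47, MECOM 4.52, PRRX2 81.0, PTCH1 15.2, RARA 51.8, SHH 1.25 and TBX5 17.7 CPM. Anterior replicate 4 held 7, all highest and mostly muscle genes: CA3 0.418, CDH15 26.2, LGR5 0.0738, MYF5 1.84, PVALB 21.7, TNNC1 39.4 and TNNT1 103 CPM. In anterior replicate 5 DDAH1 was lowest (8.60 CPM) and FOSL1 highest (52.7 CPM). In anterior replicate 2 MATN4 (8.35 CPM) and POGLUT2 (18.7 CPM) were highest, and in anterior replicate 1 SHH (0.0368 CPM, 2 reads). In posterior replicate 1 CDH15 was lowest (24.5 CPM) and ENPP6 highest (9.94 CPM), and in posterior replicate 3 DUSP3 was highest (19.4 CPM). In inhibitor replicate 1 AIFM3 (15.6 CPM) and GRHL1 (132 CPM) were highest, and in the library labelled inhibitor replicate 5 MEIS1 (52.5 CPM).

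The library labelled uninjured replicate 1 looked like a blastema and the library labelled inhibitor replicate 5 like uninjured tissue. Among 66 genes with an on and an off state, each state in at least 3 libraries and both in at least 2 groups, the states of uninjured 2 matched anterior 1, uninjured 3 matched anterior 2 and inhibitor 5 matched anterior 3, with correlations across these genes of at least 0.968, against at most 0.452 in the other 133 pairs; a candidate explanation is that the labels of libraries 34 to 37 are shifted by 1 place. A mixture with at least 5% of the other RNA is argued against by genes chosen on the other 15 libraries: 20 were on in uninjured 1 and under 5% of that level in inhibitor 5, and 10 the other way round. The best match of uninjured 1 with an anterior library was 0.0611. This cannot decide on an uninjured limb in an unusual state, which could match none if its animal gave no anterior library. Labels were kept as given, and a shift was found and tested on the same data.

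Posterior patterning genes fell with the inhibitor as a list by camera with a preset correlation (adjusted p = 1.96e-06) but not with an estimated one (0.190, and 0.299 without both doubted libraries), and 1 of 11 members passed over all genes. A lower depth is argued against by the median gene total of the inhibitor libraries, 43.1 M reads, inside the posterior range of 34.2 to 47.5 M reads. Less connective tissue cannot be told apart from a specific change: the posterior list fell by 1.19 more than the connective tissue list on the log2 scale, with an exact two-sided permutation p of 0.222, and by 0.67 more without inhibitor replicate 5 (exact permutation p of 0.4). Whether lower ERK signalling accounts for part of it cannot be decided here. The ERK feedback list fell with an estimated-correlation adjusted p of 0.0313 by camera. Without both doubted libraries that p was 0.169, with a median of −0.77 against −0.82. A fall of that list under an inhibitor of ERK activation does not tie it to the posterior genes. The ERK list was not set against the connective tissue list.

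CYP1A1 (3.37, 11.6, 58.2 and 117 CPM in inhibitor replicates 1 to 4, but 0.257 CPM in the library labelled inhibitor replicate 5, against at most 0.561 CPM in posterior libraries), AHRR and PIR were higher with the inhibitor. In uninjured tissue AHRR was at 8.96 ± 4.06 CPM, PIR at 66.6 ± 12.9 CPM and CYP1A1 at 1.56 ± 1.80 CPM (SD, n = 3). In posterior blastemas AHRR was at 3.56 ± 1.05 CPM and PIR at 24.6 ± 5.57 CPM (SD, n = 4). AHRR and PIR were thus also higher in tissue without the inhibitor, and their rise need not be a response to it. The 11 tested NRF2 targets not looked at before rose (camera adjusted p = 0.00164, median log2 fold change 0.34; 0.0332 with an estimated correlation), so an NRF2 response to the compound may contribute. With all 20 tested targets the adjusted p was 5.90e-06, and 0.0677 with an estimated correlation. Against anterior blastemas the 11 had an adjusted p of 0.00952, and 0.0745 with an estimated correlation. An aryl hydrocarbon receptor response cannot be told apart from chance in the 6 targets not looked at before (adjusted p = 0.194); with all 9 it was 0.0408, and 0.0677 with an estimated correlation (0.175 against anterior blastemas). A larger share of epithelium cannot be told apart either: the NRF2 targets rose by 0.82 more than the wound epithelium list (exact permutation p of 0.0159) while against the differentiated epidermis list the difference was −0.35 (exact permutation p of 0.167). The vehicle given to untreated blastemas is not clear, so a vehicle effect stays open as well.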

How the results depend on the processing

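The alternative without the libraries labelled uninjured replicate 1 and inhibitor replicate 5 was chosen after the data were seen; the others were set before the data were examined. The cause was not tested, unless fewer libraries or genes are the setting itself.

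For posterior against anterior blastemas, 1 gene was called, and 0 with total counts, 0 without a filter, 0 with the replicate block, 4 with the 2 groups alone and 132 with DESeq2; leaving out each library gave 0 to 0. For the inhibitor against posterior blastemas, 1576 became 699 at a 2-fold minimum, 947 with the replicate block, 983 with the 2 groups alone, 2575 without both doubted libraries (1410 shared) and 2903 with DESeq2, and 127 to 2381 leaving out a library. For anterior blastemas against uninjured tissue, 40 became 86 with RLE, 74 with total counts, 142 with the stricter filter, 8 with the 2 groups alone, 4492 without both doubted libraries and 1673 with DESeq2, and 0 to 3675 leaving out a library. For posterior blastemas against uninjured tissue, 408 became 227 at a 2-fold minimum, 265 without a filter, 45 with the replicate block, 0 with the 2 groups alone, 3108 without both doubted libraries (399 shared) and 1949 with DESeq2, and 0 to 1935 leaving out a library. For the inhibitor against anterior blastemas, 229 became 117 at a 2-fold minimum, 143 without a filter, 99 with the 2 groups alone, 898 without both doubted libraries and 1232 with DESeq2, and 36 to 828 leaving out a library.

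Gene lists called at the preset correlation were 10, 16, 13, 11 and 15 in the 5 comparisons in that order; with an estimated correlation 0, 1, 1, 1 and 2 were called, and leaving out a library gave 9 to 12, 16 to 18, 12 to 14, 11 to 13 and 14 to 17. None of these 65 called lists reversed; the others were not followed over all settings, and without both doubted libraries some of them changed direction, such as the stress list in posterior against uninjured. Of the 65, 2 were no longer called without both doubted libraries, connective tissue matrix and hedgehog targets in posterior against uninjured. The replicate block kept all calls and added 3. The share of posterior-anterior genes moved toward anterior levels rests on 1 gene, so its value says nothing about stability.

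Of 221 named gene results, 60 kept direction and side of the threshold in every setting run; 9, with adjusted p of 0.691 or more, reversed in at least 1. With the replicate block MEIS1 under the inhibitor against posterior was −0.11, and HAND2 and HOXA11 in anterior against uninjured 0.20 and 0.14. Without both doubted libraries these were −0.21, 1.15 and 0.65, and in posterior against uninjured MEIS2 was 0.10 and ALDH1A2 −0.12. Leaving out a library gave −0.12 to 0.12 for ETV4 (posterior against anterior) and −0.21 to 0.11 for MEIS1 under the inhibitor. In anterior against uninjured it gave −0.55 to 1.15 for HAND2, −0.28 to 0.0096 for MEIS1 and −0.59 to 0.65 for HOXA11, and in posterior against uninjured −0.34 to 0.094 for MEIS2 and −0.13 to 0.75 for ALDH1A2. In inhibitor against anterior it gave −0.53 to 1.18 for HAND2 and −0.30 to 1.19 for HOXA11.

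By the data, the replicate numbers do not pair the libraries: correlations of same-numbered libraries ran from −0.243 to 0.339, and in none of the comparisons did every library match its own number best. The names of uninjured and anterior libraries 1 to 3 do share a stem, and the labels do not say what it marks. The on/off genes matched uninjured 2 with anterior 1 and uninjured 3 with anterior 2 instead (same-numbered uninjured and anterior libraries reached 0.00575 to 0.194). The replicate block (48 genes) goes by the numbers, so no fit here takes those matches into account. Genes near 0 reads, such as SHH in anterior blastemas, are limited by depth.

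Of the splits of the same libraries, the real one included, 4 of 100 called at least 1 gene for posterior against anterior (highest other 48), while a first draw of 50, part of the same 100, gave 3, a share of 0.06. Whether chance is excluded at 0.05 for this 1 gene thus depends on the draw. For the inhibitor against posterior, 2 of 100 called at least 1576 (highest other 1832, the split that puts inhibitor replicate 4 with the posterior libraries). For anterior against uninjured, 2 of 56 called at least 40. The highest other, 1328, exchanges uninjured replicate 1 with anterior replicate 4, and why it called so many genes was not tested. Of the 56 splits, 8 part the 3 pairs that share a stem, too few for a share under 0.05 (real 40, highest other 0). For posterior against uninjured, 1 of 35 called at least 408 (highest other 2), and for the inhibitor against anterior 2 of 100 called at least 229 (highest other 397). For the inhibitor against posterior and posterior against uninjured, chance is excluded at 0.05 only for separate animals and correct labels, both in doubt. It stays open for anterior against uninjured and the inhibitor against anterior. Their splits ignore on/off matches (also inhibitor 5 with anterior 3), and the 8 splits go by stems. For posterior against uninjured, injury cannot be told from what the letters A and P mark.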

Other observations

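The comparisons in this part leave out the libraries labelled uninjured replicate 1 and inhibitor replicate 5, a choice made after the data were seen. The genes follow the report's rule except for the minimum level. Here the log2 CPM of the libraries were averaged, where the report's rule took an average CPM on the log2 scale. Genes near 0 in most libraries, such as CYP1A1, can thus be missing. With 2 uninjured libraries left, anterior blastemas had higher levels of the cytokine gene IL11, 96.4 ± 79.9 CPM (SD, n = 5) against 0.281 ± 0.127 CPM (SD, n = 2), of CYP27B1, which activates vitamin D, 99.9 ± 54.4 CPM (SD, n = 5) against 1.10 ± 0.223 CPM (SD, n = 2), and of the leptin gene LEP, 9.99 ± 5.70 CPM (SD, n = 5) against 0.0656 ± 0.0229 CPM (SD, n = 2). SHD was at 59.6 ± 22.4 CPM (SD, n = 5) against 0.313 ± 0.0585 CPM (SD, n = 2), and WNT9B at 6.82 ± 2.15 CPM (SD, n = 5) against 0.0494 ± 0.0699 CPM (SD, n = 2). All 5 passed the edgeR threshold. Posterior blastemas showed the same 5 genes among their 10 highest, with CYP27B1 at 305 ± 93.8 CPM (SD, n = 4) and SHD at 54.8 ± 20.9 CPM (SD, n = 4). Among the falls were muscle genes in anterior blastemas, MYL10 from 1691 to 25.3 CPM and TNNC1 from 512 to 10.1 CPM, and in posterior blastemas ELN, the elastin gene, from 169 to 24.9 CPM. Of 28 cell cycle genes, 18 rose in anterior and 7 in posterior blastemas (camera adjusted p = 6.79e-09 and 4.24e-06, and adjusted p = 0.481 and 0.558 with an estimated correlation). Between both sides, 0 of the 28 genes were called higher and 0 lower in edgeR. As a list they were lower in posterior than in anterior blastemas by camera with a preset correlation (median log2 fold change −0.176, adjusted p = 0.002445). With an estimated correlation that list had adjusted p = 0.6819.

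Without the same libraries, the clock genes PER1 (log2 fold change 4.45 ± 0.92, SE) and CIART (log2 fold change 2.40 ± 0.71, SE) were higher in posterior blastemas with the inhibitor than without it. So were the cystine transporter gene SLC7A11 (2.93 ± 0.51, SE), OSGIN1 (2.80 ± 0.48, SE) and CYP51A1 of sterol synthesis (2.42 ± 0.54, SE). ADAMTS9 (−2.11 ± 0.26, SE) and CYP27B1 (−2.03 ± 0.59, SE), the gene that rose in both kinds of blastema, were lower. The vehicle given to untreated blastemas is not clear, so a vehicle effect cannot be told apart from one of the inhibitor. The NOTCH list fell (median −0.60 over 10 genes, 3 calls, camera adjusted p = 0.0412; adjusted p = 0.299 with an estimated correlation).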
